A study of Mus musculus with 8 samples.

How the data were processed

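MicroRNAs (miRNAs) were measured in cell culture medium with 1-colour Agilent mouse miRNA arrays, on which each miRNA is read by several probe spots and Cy3-labelled small RNA gives the signal. Per the labels' protocols, primary myocytes from the leg muscle of newborn mice were grown as transwell co-cultures, in which a bottom chamber seeded with 2.5 and an insert seeded with 1.5 (both in 1e5 cells) shared medium across a membrane with pores of 0.4 µm. The mice carried a human SOD1 transgene, either wild-type (WT) or with the G93A mutation that gives mice a form of amyotrophic lateral sclerosis (ALS). Medium was collected at 2 days in vitro, RNA was extracted from 600 µl of it with TRIzol LS, and 150 ng of small RNA was labelled, per the labels' protocols. The proliferation medium held 10% foetal bovine serum and was replaced at 2 days in vitro by differentiation medium with 2% horse serum, and the labels do not name the medium that was collected. A probe cannot tell a mouse miRNA from a bovine or equine one of the same sequence. Medium that had held no cells was not analysed here.

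The 8 arrays formed 3 groups, written as bottom chamber/insert: WT/WT (n = 2), G93A/WT (n = 3) and G93A/G93A (n = 3). The reverse mixed combination, which the labels' protocols also describe, was not analysed here. The labels call each sample a biological replicate and name no litter, culture day or batch. All 8 arrays came from 1 slide with 2 rows and 4 columns. Row 1 held WT/WT 1 and the G93A/WT arrays, and row 2 held WT/WT 2 and the G93A/G93A arrays, so G93A/WT and G93A/G93A never shared a row and the rows are linked only through 1 WT/WT array each. A fit with the slide row as a block therefore compares each of these groups with the 1 WT/WT array of its row, as a fit within that row does. The WT/WT arrays alone filled column 1.

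The deposited array files give an intensity per miRNA on a linear scale (the total gene signal), its error and a detected flag, per the file headers. The scanner software's version and its background method are not given in the sources used here. In the deposited files an undetected miRNA is listed at 0.1, and the number of detected miRNAs per array was identical when detection was taken as a signal above 3 times its own error. A deposited table of the authors' processed values of the same arrays is also an intensity on a linear scale, judged from its values, and is not centred. Its normalization is not given in the sources used here. It held 492 mouse miRNAs and 10 control features, the 492 being exactly the miRNAs detected on all arrays of at least 1 group. Its array medians ran from 25.4 to 28.1. Across the miRNAs detected on an array, its log2 values correlated with the log2 gene signals of that array at r = 0.970 to 0.999. It was used as an alternative, and the method that put its arrays on one scale stays unknown.

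Each array's signals were scaled so that the 75th percentile over the 423 mouse miRNAs detected on all 8 arrays was equal between arrays. A floor was then set at 1.52 signal units (log2 0.60), the median over arrays of the lowest scaled signal of a detected miRNA, and log2 was taken. The scale factors ran from 0.593 to 1.44. Of 1881 mouse miRNAs, 1295 were detected on no array and 48 on 1 array. The 538 detected on at least 2 arrays were tested. The number of arrays, 2 or 3 per group, limits the precision.

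Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 spread shared by the 3 groups, prior degrees of freedom 1.96), with Benjamini-Hochberg adjustment over the 538 miRNAs and a threshold of 0.05. Unless another test is named, every adjusted p of a miRNA is from this limma test. An SE beside a log2 difference is limma's moderated standard error. A miRNA undetected on every array of a group has only a bound there. Its difference is given as at least N-fold, the mean of the group in which it was detected against the dim group's mean of each array's lowest detected signal, beside the adjusted p of the fit. Detection is judged per miRNA, so an undetected miRNA may lie above that lowest signal. Each such N is therefore approximate and not a sure minimum. Where a group has some or all arrays at the floor, the log2 difference, its SE and its adjusted p depend on the floor. Arrays at the floor add no spread, so such an adjusted p may be too small. Lists of miRNAs were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with limma's fry beside it. Of 12 lists, the 10 with at least 3 tested members were tested as sets. Counts per list are given over all 538 miRNAs and adjusted over the list alone. Numbers of detected miRNAs were compared with exact permutation tests, 2-sided, which cannot give a p below 0.1 here.

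The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. The lists covered muscle-enriched miRNAs, regulators of myoblasts, inflammation, the let-7 family, miR-17-92 and its paralogues, the Dlk1-Dio3 locus, miRNAs reported in ALS, and markers of fibroblasts, erythroid cells and serum, leukocytes and platelets, endothelium and neural cells. The naming rule took, per comparison and direction, the 8 passing miRNAs with the largest log2 difference. Where fewer passed, it was filled up by unadjusted p. It added the 4 members of each list with the highest mean signal, the 10 miRNAs with the highest mean signal and 10 miRNAs chosen for muscle or ALS. It also added up to 5 miRNAs per direction that were detected on all arrays of one group and on none of the other. Signals of different probes do not rank miRNAs by amount. A list of epithelial miRNAs was written after the values had been seen. Names are those of the array. Of the 538 tested miRNAs, 504 matched 1 gene in a table for the assembly GRCm38.p6, 1 matched several and 33 matched none. No coordinates are given. Members of one family with near-identical sequences (let-7, miR-133a and miR-133b, miR-199a and miR-199b) may share signal, so their separate values are uncertain.

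The alternatives covered scaling (median, quantile, none, the authors' values), the filter on detection, the floor, the spread model, array weights, the samples in the fit, the replicate number or slide row as a block, and leaving out each array. Alternatives added after the data were seen were the slide column as a random block, fits within 1 slide row, the filter of the authors' table, scaling on miRNAs numbered below 1000, centring each probe class on each array, and leaving out of the fit the 1 tested miRNA (miR-433-5p) that lay at the floor on every array. A miRNA without spread distorts the shared spread estimate. In settings where over 1 percent of the miRNAs were at the floor on every array, such miRNAs were therefore left out of the fit, a handling chosen after the result without it was seen. Scaling on the 75th percentile over all mouse miRNAs was not run, because that percentile was the constant for undetected miRNAs on 3 arrays.

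The fit was tested on simulated data of 538 miRNAs with 100 miRNAs changed 2-fold and 100 changed 4-fold. For G93A/G93A against WT/WT it recovered 87% of the smaller and 89% of the larger changes, with 11 false calls among 201. For G93A/WT against WT/WT it recovered 80% and 93%, with 8 false calls among 192, and for G93A/G93A against G93A/WT 85% and 96%, with 18 false calls among 216. A list of 21 further miRNAs that was shifted by a smaller amount passed the set test in each of the 3 comparisons, and an unshifted list did not. The simulated noise was independent between miRNAs and held no effect of slide row. Far more miRNAs were changed than passed in the real comparisons, which eases the Benjamini-Hochberg threshold. The recovered shares may therefore overstate those in the real data.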

Results

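The series asked which miRNAs muscle cells release when they carry the G93A mutation of human SOD1, and how that differs when mutant and wild-type cells share medium. Culture medium of 8 transwell co-cultures of primary mouse myocytes was measured on 1 array each: 2 of WT/WT, 3 of G93A/WT (G93A in the bottom chamber, WT in the insert) and 3 of G93A/G93A. Between 450 and 563 of the 1881 mouse miRNAs on the array were detected per sample, and 423 were detected in all 8. The sum of all signals per array ran from 115265 to 203040 units, highest on G93A/WT 2. The 3 brightest miRNAs took 39.7% to 48.1% of that sum. Arrays of one group correlated at r = 0.970 to 0.990 across the tested miRNAs, and arrays of different groups at r = 0.939 to 0.984. The first principal component held 45.4% of the variance and the second 24.8%.

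**Figure D1:**
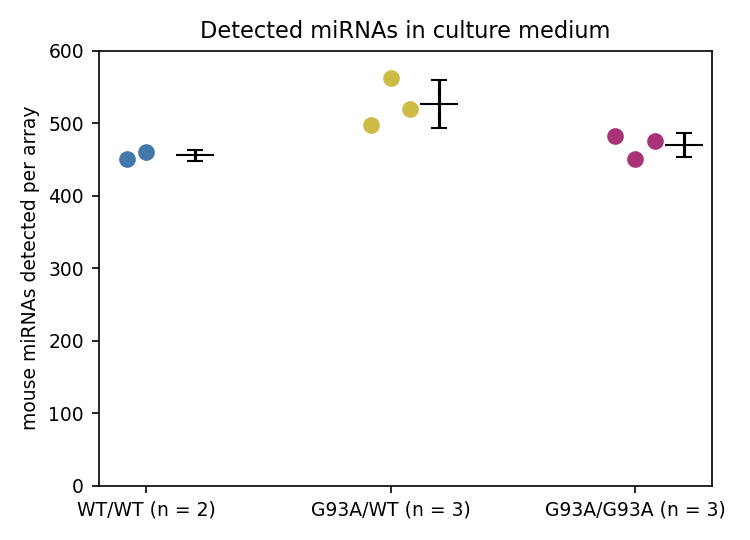
Number of mouse miRNAs detected per array (vertical axis) in WT/WT, G93A/WT and G93A/G93A medium. Each point is 1 array, and the bar beside the points is the group mean with its SD. The G93A/WT arrays lie between 497 and 563, and the other 5 arrays between 450 and 483.

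The brightest miRNAs in the medium were miR-8110, miR-3960 and miR-5126, with log2 scaled signals of 15.32 ± 0.03, 14.33 ± 0.19 and 13.92 ± 0.02 in WT/WT (SD, n = 2). The other brightest were miR-1224-5p, miR-6931-5p, miR-2861, miR-6769b-5p, miR-206-3p, miR-211-3p and miR-6366. The muscle-specific miR-206-3p stood at 11.51 ± 0.33 in WT/WT (SD, n = 2), 11.27 ± 0.19 in G93A/WT (SD, n = 3) and 11.24 ± 0.03 in G93A/G93A (SD, n = 3). Its partner miR-133b-3p, transcribed from the same locus, stood at 10.26 ± 0.22, 10.57 ± 0.12 and 10.51 ± 0.32 in the same order. The muscle miRNAs miR-133a-3p (8.95, 9.52 and 9.12) and miR-1a-3p (7.41, 7.38 and 7.49) were dimmer. None of the 5 tested muscle-enriched miRNAs passed the test in any of the 3 comparisons, nor adjusted over the list alone. The list does not hold miR-133a-5p, the other arm of miR-133a, named after its values were seen. It was dim, at a mean of 1.59 in G93A/WT, and was detected on every G93A/WT array and on no other. The difference between G93A/G93A and WT/WT was −0.27 ± 0.17 for miR-206-3p (SE, adjusted p = 0.351) and 0.18 ± 0.39 for miR-133a-3p (SE, adjusted p = 0.829). The median and the mean of this list had opposite signs in that comparison (0.08 and −0.01) and between G93A/WT and WT/WT (−0.03 and 0.06). The erythrocyte and serum miRNA miR-451a stood at 9.78, 10.23 and 10.02, and miR-92a-3p, also abundant in serum, at 10.12, 10.05 and 10.12.

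More miRNAs were detected in G93A/WT medium (527 ± 33.5, SD, n = 3) than in WT/WT (456 ± 7.78, SD, n = 2) or G93A/G93A medium (470.0 ± 16.8, SD, n = 3). In exact permutation tests, 2-sided, p was 0.2 for G93A/WT against WT/WT, 0.1 for G93A/G93A against G93A/WT and 0.3 for G93A/G93A against WT/WT, and 0.1 is the smallest value these tests can give. The G93A/WT arrays were also the brightest, with a mean scale factor of 0.760 ± 0.170 against 1.28 ± 0.216 in WT/WT and 1.15 ± 0.168 in G93A/G93A (SD). 12 miRNAs, among them miR-1945, miR-7009-5p and miR-452-5p, were detected on all G93A/WT arrays and on no other, and 0 miRNAs were detected on all arrays of either other group alone.

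**Figure D2:**
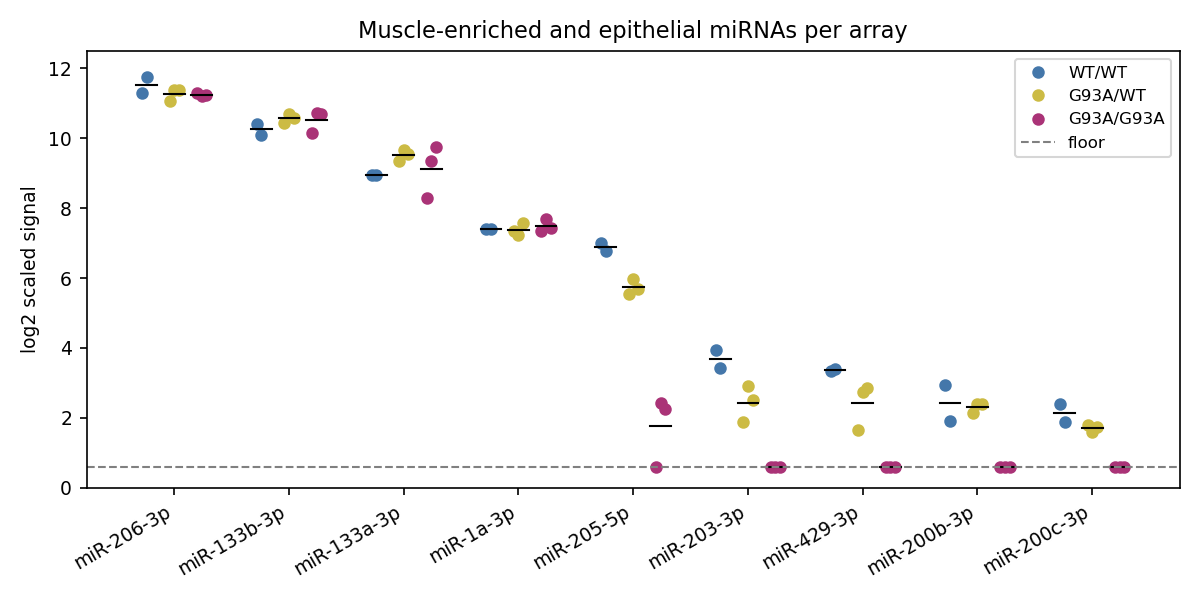
Log2 scaled signal (vertical axis) of 4 muscle-enriched and 5 epithelial miRNAs on each of the 8 arrays. Points are arrays coloured by group, black lines are group means and the dashed line is the floor at 0.60. miR-205-5p lies at a mean of 6.88 in WT/WT, 5.73 in G93A/WT and 1.75 in G93A/G93A, while miR-206-3p lies between 11.24 and 11.51 in the group means.

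Among the largest decreases in G93A/G93A medium against WT/WT medium were 5 miRNAs known from epithelia. miR-205-5p, abundant in skin and other stratified epithelia, was lower by a log2 difference of −5.12 ± 0.51 (SE, adjusted p = 0.00301), from 6.88 ± 0.16 in WT/WT to 1.75 ± 1.00 in G93A/G93A, where 2 of 3 arrays detected it. miR-203-3p, a miRNA of differentiating keratinocytes, was at least 7.73-fold lower (adjusted p = 0.00301), and 3 members of the miR-200 family, which maintains the epithelial state, were lower as well: miR-429-3p at least 6.23-fold, miR-200b-3p at least 3.26-fold and miR-200c-3p at least 2.67-fold. These 4 were detected on no G93A/G93A array. Among miRNAs that act in myoblasts, miR-181a-5p was at least 3.29-fold lower (adjusted p = 0.000891), and miR-125b-5p was lower by −0.79 ± 0.11 (SE, adjusted p = 0.00929).

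In this comparison 46 of 538 miRNAs passed, 20 higher and 26 lower in G93A/G93A, and 143 had an unadjusted p under 0.05. The median difference over all tested miRNAs was −0.01. Also among the 8 largest decreases were miR-17-3p (at least 2.71-fold) and miR-212-3p (at least 2.60-fold). On the higher side, miR-3097-5p (at least 6.73-fold, adjusted p = 0.0461), miR-6913-5p (at least 3.41-fold), miR-7647-3p (at least 3.06-fold) and miR-7078-5p (at least 2.43-fold) were detected on all G93A/G93A arrays and on no WT/WT array. miR-8119 was higher by 2.18 ± 0.31 and miR-7043-5p by 1.30 ± 0.28 (SE), each detected on 1 of 2 WT/WT arrays. miR-466j was higher by 1.88 ± 0.42 and miR-6957-5p by 1.05 ± 0.19 (SE). miR-294-3p was also detected on all G93A/G93A arrays and no WT/WT array, and did not pass (adjusted p = 0.188). Of the 31 passing miRNAs detected on all arrays of both groups, 14 were higher, among them miR-423-5p (0.65 ± 0.12, SE) and miR-6370 (0.60 ± 0.11, SE), and 17 were lower.

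Of 21 tested regulators of myoblast proliferation and differentiation, 5 were lower, none was higher and 16 did not pass (8 lower and 0 higher adjusted over the list alone), and 19 lay below zero, with a median of −0.37, also with the 1 undetected member at its bound. The list was the only one of 10 that passed camera (adjusted p = 7.37e-05; 5 lists had an unadjusted p under 0.05), and it did not pass with an estimated correlation (adjusted p = 0.819 with an estimated correlation), where 0 lists passed and 0 had an unadjusted p under 0.05 in limma's camera. The 5 were miR-181a-5p and miR-378a-3p (−0.65 ± 0.15), both known to promote myoblast differentiation, miR-125b-5p, known to restrain it, and miR-23a-3p (−0.53 ± 0.12) and miR-23b-3p (−0.76 ± 0.14, all SE); miR-378a-3p and miR-23b-3p were named after their values were seen. The bright members miR-24-3p (−0.37, adjusted p = 0.108) and miR-27a-3p (−0.37, adjusted p = 0.483) did not pass. With fry its adjusted p was 0.0331. With the slide row as a block the median was −0.43 (camera adjusted p = 6.48e-05). Within row 2 it was also −0.43, because both fits compare G93A/G93A with WT/WT 2 alone. Over 29 alternatives the adjusted p ran from 1.69e-05 to 0.819, passing in 28, with a median below zero in each. Apart from fry and the estimated correlation (the 1 that did not pass), these kept camera's preset correlation and so did not test it. All 21 are numbered below 1000, and the median over all tested miRNAs numbered below 1000 was −0.105. With each probe class centred the list's median was −0.29 (camera adjusted p = 0.00258).

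**Figure D3:**
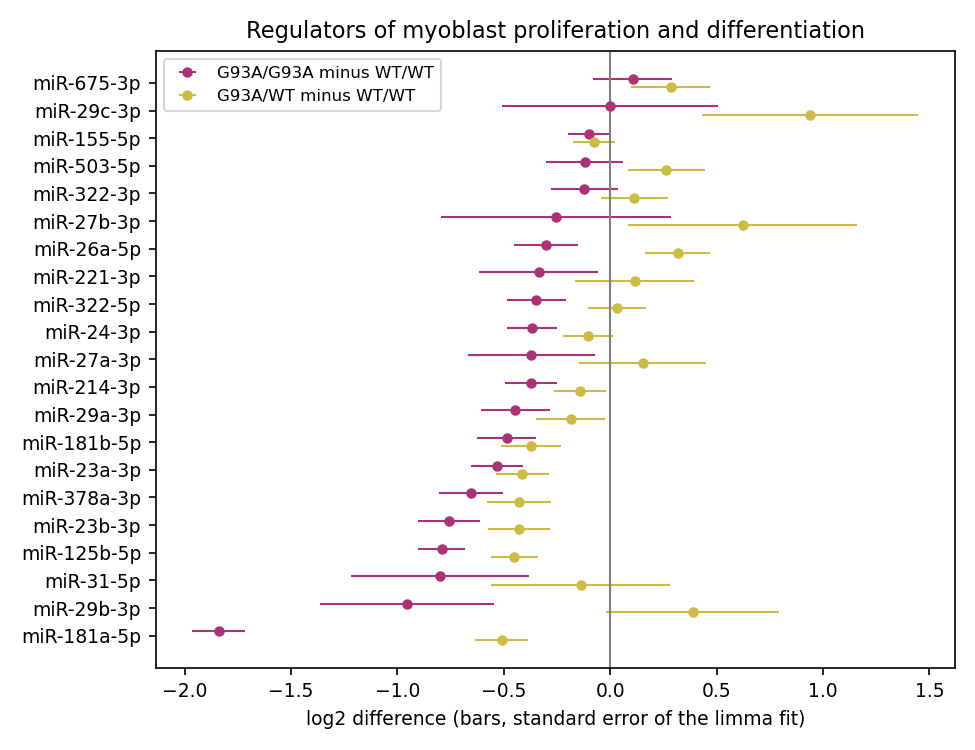
Log2 differences (horizontal axis) of the 21 tested regulators of myoblast proliferation and differentiation in G93A/G93A minus WT/WT and in G93A/WT minus WT/WT. Points are limma estimates and bars their SE. In the first comparison 19 of the 21 lie below zero, with a median of −0.37, and in the second 11 lie below zero, with a median of −0.08.

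None of the other lists passed the set test between G93A/G93A and WT/WT in this fit. The Dlk1-Dio3 list (median −0.12, adjusted p = 0.0328, 0.0103 to 0.819 over 29 alternatives, passing in 8) and the let-7 list (median −0.29, adjusted p = 0.0467, 0.0144 to 0.954, passing in 3) passed camera as well with the slide row as a block. Within row 2, with 1 WT/WT array, these 2 passed (adjusted p = 0.0378 and 0.0144), and so did the inflammation list (median −0.34, adjusted p = 0.0384, 0.0371 to 0.819, passing in 4). These calls use the preset correlation, and with an estimated correlation, without the block, the adjusted p was 0.819 for Dlk1-Dio3, 0.954 for let-7 and 0.819 for inflammation. Of 44 tested miRNAs of the imprinted Dlk1-Dio3 locus, 6 were lower and none higher (6 and 0 adjusted over the list alone; median −0.13, also −0.13 with undetected members at their bound; camera adjusted p = 0.0629), including miR-411-3p (−1.19 ± 0.14, SE) and miR-127-3p (−0.63 ± 0.11, SE). The bright members miR-434-3p (−0.12) and miR-410-3p (−0.39) did not pass. Among 11 inflammation-related miRNAs, miR-223-3p, a myeloid miRNA, was higher by 0.52 ± 0.12 (SE, adjusted p = 0.0433), miR-125b-5p and miR-203-3p were lower, and 8 did not pass, among them miR-155-5p (−0.10) and miR-146a-5p (0.34); adjusted over the list alone 1 was higher and 3 lower (camera adjusted p = 0.0907). Of 16 miRNAs reported in ALS, miR-125b-5p, miR-23a-3p and miR-199a-5p (−0.85 ± 0.17, SE) were lower, also adjusted over the list alone, and 13 did not pass (camera adjusted p = 0.0907). miR-199a-5p, named after its values were seen, was also the 1 of 7 fibroblast miRNAs that passed (3 lower adjusted over the list alone), and all 7 lay below zero (median −0.33, camera adjusted p = 0.0629). None of 9 let-7 miRNAs, of 9 members of miR-17-92 and its paralogues, or of 7 erythroid and serum miRNAs passed, nor adjusted over the list alone (camera adjusted p = 0.221, 0.985 and 0.957). Of 3 leukocyte and platelet miRNAs, miR-223-3p was higher and 2 did not pass (1 higher adjusted over the list alone, camera adjusted p = 0.936). The median and the mean were of opposite sign for the erythroid (−0.01 and 0.12) and leukocyte (−0.10 and 0.08) lists. The 1 tested endothelial miRNA, miR-126a-3p (−0.23), and the 2 tested neural ones, miR-128-3p (0.06) and miR-338-3p (−0.24), did not pass.

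The epithelial list was drawn up after these values were seen. It holds 10 miRNAs, 5 of which were tested, and all 5 were lower in G93A/G93A than in WT/WT beside the myoblast regulators; with the slide row as a block 4 of 5 still passed, and within row 2, where 1 WT/WT array remains, 2 of 5. With the slide row as a block 7 miRNAs passed in the whole comparison (1 higher, 6 lower), where all 46 kept their sign, their median size moved from 0.82 to 0.80 and their median SE rose from 0.145 to 0.169. Within row 2 there were 3 calls (0 higher, 3 lower). The count fell to 7 without WT/WT 1, to 21 without WT/WT 2 and to 21 without G93A/G93A 2, and it was 18 (4 higher, 14 lower) when miRNAs numbered below 1000 and those numbered 1000 or above were each centred on each array. Scaling on the median gave 5 higher and 28 lower in place of 20 and 26.

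The miRNAs called between G93A/WT medium, which G93A and WT cells shared, and WT/WT medium were mainly dim. Of 17 miRNAs that were higher, 12 were detected on no WT/WT array, led by miR-1945 (at least 4.30-fold, adjusted p = 0.000494) and miR-6913-5p (at least 3.71-fold, adjusted p = 0.046). Arrays at the floor add no spread, so the adjusted p of these 12 may be too small. miR-8119 was higher by 2.02 ± 0.31 and miR-7043-5p by 1.77 ± 0.28 (SE). Only 4 miRNAs were lower: miR-411-3p (−0.76 ± 0.14), miR-181d-5p, a relative of miR-181a (−0.67 ± 0.10), miR-6947-5p (−0.62 ± 0.13) and miR-6960-5p (−0.59 ± 0.11, all SE). The epithelial miR-205-5p and the other 4 tested members of that list did not pass (5 below zero, median −0.95).

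In this comparison 21 of 538 miRNAs passed, 17 higher and 4 lower, and 132 had an unadjusted p under 0.05. The median difference over all tested miRNAs was 0.04. The other leading increases were in miR-7009-5p (at least 2.91-fold), miR-682 (at least 2.73-fold), miR-452-5p (at least 2.42-fold) and miR-7078-5p (at least 2.37-fold). miR-7060-5p, miR-7647-3p and miR-365-2-5p were detected on all G93A/WT arrays and on no WT/WT array but did not pass (adjusted p = 0.0793, 0.0512 and 0.157). On the lower side miR-127-3p (−0.51), miR-1224-5p (−0.51), miR-30c-2-3p (−0.49) and miR-2137 (−0.47) did not pass (adjusted p = 0.053 for each). Of the 7 passing miRNAs detected on all arrays of both groups, 3 were higher and 4 lower.

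None of the 10 lists passed camera between G93A/WT and WT/WT, and 0 had an unadjusted p under 0.05. With limma's fry 0 passed. Of the 21 myoblast regulators none passed (0 higher and 2 lower adjusted over the list alone, median −0.08, camera adjusted p = 0.924), with miR-125b-5p at −0.45 and miR-181a-5p at −0.51 (adjusted p = 0.0611 for each). With the slide row as a block the list's median was −0.04, within row 1 also −0.04. Of the 44 miRNAs of the Dlk1-Dio3 locus, 1 was higher and 1 lower (1 higher and 2 lower adjusted over the list alone), and these were the 2 arms of one precursor: miR-411-5p, undetected in WT/WT, was at least 2.02-fold higher (adjusted p = 0.000741), and miR-411-3p was lower. miR-411-5p was named after its values were seen. It was undetected on every WT/WT and G93A/G93A array, so its spread in the fit came from the G93A/WT arrays alone. None of the 11 inflammation-related miRNAs passed (1 higher and 2 lower adjusted over the list alone), with miR-223-3p at 0.43 (adjusted p = 0.0793). None of the ALS-reported, fibroblast, let-7, miR-17-92, erythroid, leukocyte, endothelial or neural miRNAs passed. Adjusted over the list alone, 1 leukocyte miRNA was higher, and no member of these other lists passed.

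Among the 423 miRNAs detected on all 8 arrays 0 passed in limma (103 at an unadjusted p under 0.05), a filter that leaves out the 12 miRNAs undetected in WT/WT by its own rule. The 7 calls that remain in it, including the 4 lower ones, kept their log2 differences, and their median SE was 0.139 against 0.137 before. The split into higher and lower calls depended on the scaling: it was 6 and 13 with quantile normalization, 16 and 11 with scaling on the median and 1 and 3 with the authors' values. Without scaling it was 130 and 0, but there the median difference of all tested miRNAs lay at 0.79, a shift large enough to put the 4 lower miRNAs above zero. With the slide row as a block 16 passed (16 higher, 0 lower), 10 of them from the 21. All 21 kept their sign there, their median size stayed at 1.04 and their median SE rose from 0.141 to 0.183. Of the 4 lower miRNAs, miR-411-3p lay at −0.82 and miR-181d-5p at −0.74 with the block. A fit within row 1 gives the same differences, since both compare G93A/WT with WT/WT 1 alone. The count was 7 without WT/WT 1, 12 without G93A/WT 2, 35 without G93A/WT 1 and 61 without G93A/G93A 3.

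In G93A/G93A medium against G93A/WT medium, which also holds what the WT cells released, the 5 tested epithelial miRNAs, a list drawn up after the values were seen, were among the lower calls. miR-205-5p was lower by −3.98 ± 0.46 (SE, adjusted p = 0.00202), and miR-203-3p (at least 3.27-fold), miR-429-3p (at least 3.24-fold), miR-200b-3p (at least 3.00-fold) and miR-200c-3p (at least 1.98-fold) fell below detection. With the slide row as a block 0 of 5 passed in limma, with a fitted difference of −3.75 for miR-205-5p (−3.98 before). The fitted differences of the other 4 depend on the floor. With the block they shrank for miR-203-3p (from −1.84 to −1.31), miR-200b-3p and miR-200c-3p, and not for miR-429-3p. miR-1945 (at least 4.49-fold, adjusted p = 0.000263) and miR-7009-5p (at least 3.05-fold) were likewise undetected in G93A/G93A. miR-6370, miR-6957-5p and miR-883a-5p were higher in G93A/G93A by 1.00 ± 0.10, 0.97 ± 0.17 and 0.95 ± 0.09 (SE).

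In this comparison 57 of 538 miRNAs passed, 29 higher and 28 lower, and 173 had an unadjusted p under 0.05. The median difference over all tested miRNAs was −0.10. All 29 higher miRNAs were detected on all arrays of both groups, while 18 of the 28 lower ones were detected on no G93A/G93A array. The other leading increases were in miR-882 (0.92 ± 0.12), miR-1966-5p (0.90 ± 0.10), miR-7084-5p (0.90 ± 0.11), miR-5113 (0.86 ± 0.12) and miR-423-5p (0.81 ± 0.11, all SE). Lower by the rule were also miR-3075-5p (−1.84 ± 0.38, SE), detected on 2 of 3 G93A/G93A arrays, and miR-682, at 2.24 ± 0.12 in G93A/WT (SD, n = 3) and detected on 1 of 3 G93A/G93A arrays. miR-181a-5p was at least 2.31-fold and miR-17-3p at least 2.21-fold lower.

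The myoblast regulators were the only list that passed camera in this fit (adjusted p = 0.0026; 3 lists had an unadjusted p under 0.05), and this call was lost with an estimated correlation (adjusted p = 0.850 with an estimated correlation). Of 21 tested, miR-181a-5p and miR-26a-5p (−0.62 ± 0.14, SE), known to promote myoblast differentiation and named after its values were seen, were lower and 19 did not pass (2 lower adjusted over the list alone). All 21 lay below zero, with a median of −0.34, also with undetected members at their bound. These 21, like the 7 fibroblast miRNAs below, are all numbered below 1000. Over all tested miRNAs numbered below 1000 the median in this comparison was −0.20, against 0.05 for those numbered 1000 or above. With fry the adjusted p was 0.0409. With the slide row as a block the median was −0.41 (adjusted p = 0.0126), and with each probe class centred it was −0.17 and did not pass (adjusted p = 0.238), the adjusted p running from 0.00135 to 0.850 over 28 alternatives. The let-7 list (median −0.51, −0.27 before; adjusted p = 0.0126, 0.0126 to 0.895 over 28 alternatives, passing in 4) and the Dlk1-Dio3 list (median −0.17; adjusted p = 0.0249, 0.0129 to 0.948, passing in 8) passed as well with the slide row as a block. With an estimated correlation, without the block, the adjusted p was 0.850 for each of these 2 lists and for the fibroblast list. All 7 fibroblast miRNAs lay below zero (median −0.47, camera adjusted p = 0.0512; the list passed in 12 of 28 alternatives), and none of the 7 passed. Of the 44 Dlk1-Dio3 miRNAs, miR-411-5p (at least 2.11-fold), miR-379-5p (−0.57 ± 0.10) and miR-431-5p (−0.42 ± 0.10, SE), the last pair named after their values were seen, were lower (2 adjusted over the list alone, camera adjusted p = 0.0512). Among inflammation-related miRNAs miR-203-3p was lower and 10 did not pass (5 lower adjusted over the list alone, camera adjusted p = 0.129). None of the listed ALS-reported, let-7, miR-17-92, muscle, erythroid, leukocyte, endothelial or neural miRNAs passed, nor adjusted over the list alone. The unlisted miR-133a-5p was detected on every G93A/WT array and on no G93A/G93A array.

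G93A/WT and G93A/G93A lay in different slide rows, and with the row as a block 0 miRNAs passed in limma (73 at an unadjusted p under 0.05), a fit in which the rows are linked only through the 2 WT/WT arrays. All 57 kept their sign there, and their median size moved from 0.84 to 0.76 while their median SE rose from 0.113 to 0.227. The count was 121 without G93A/G93A 3 and 37 without G93A/G93A 2. Without scaling the median moved to −0.68 and the split to 1 higher and 148 lower, with quantile normalization the split was 29 and 12, and with the authors' values 40 and 6.

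Among the 3 groups as a whole, 77 of 538 miRNAs passed limma's F test, and 188 had an unadjusted p under 0.05. Without single arrays the count was 41 (without G93A/WT 2), 44 (without WT/WT 1), 45 (without G93A/G93A 2) and 125 (without G93A/G93A 3), and with the slide row as a block it was 28. The comparisons of G93A/G93A and of G93A/WT with WT/WT shared 7 calls. Of these 5 were higher in both, among them miR-8119, miR-6913-5p, miR-7043-5p and miR-7078-5p, and 2 were lower in both, miR-411-3p and miR-181d-5p. None was opposite. Independent lists would share 0.632 higher and 0.193 lower calls, a value that does not allow for the shared WT/WT arrays. Across miRNAs, which are not independent replicates, the log2 differences of the 2 comparisons correlated at r = 0.495 (rho = 0.481), against r = 0.597 ± 0.058 (SD) in 100 simulations of unchanged groups that share the WT/WT arrays. The covariance was 0.166 against a simulated 0.0473, a difference of 0.119, and 64.9% of signs were shared against a simulated 70.5%. Changes in either group alone lower the correlation and the share of signs, so values below the simulated ones cannot decide on a shared change. The 2 WT/WT arrays could be split only into single arrays, so part of the overlap and of the correlation may come from these shared controls.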

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

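The control features below were compared only after the data were seen. Outside the mouse miRNAs, 10 of the 21 control features on the array were detected on all 8 arrays, and 2 of them were above their level in WT/WT on every array of a group. hur_4 had a mean scaled signal of 1227 ± 122 (SD, n = 3) in G93A/WT and 1201 ± 111 (SD, n = 3) in G93A/G93A, against 1030 ± 22.2 (SD, n = 2) in WT/WT, ratios of 1.19 and 1.17. hur_6 had 365 ± 54.2 (SD, n = 3) in G93A/WT against 300.1 ± 3.02 (SD, n = 2) in WT/WT, a ratio of 1.22. These are 3 of 20 pairs of feature and group, where chance alone gives 10%. In the other direction also 3 of the 20 pairs lay below WT/WT on every array of a group. miRNABrightCorner30 had 567 ± 93.3 in G93A/WT and 778 ± 132 in G93A/G93A (SD, n = 3), against 1229 ± 3.43 in WT/WT (SD, n = 2), ratios of 0.461 and 0.633. hur_6 had 215 ± 48.0 in G93A/G93A (SD, n = 3), a ratio of 0.716. All these values carry the scale factors of the mouse miRNAs, which a control feature need not follow, so the ratios depend on the scaling. Unscaled means in G93A/WT, G93A/G93A and WT/WT were 753, 677 and 971 for miRNABrightCorner30. They were 1695, 1068 and 812 for hur_4 and 508, 194 and 237 for hur_6. The WT/WT arrays themselves lay far apart in dmr_3 (5090 on WT/WT 1 and 255 on WT/WT 2, 359 to 1052 on the other arrays) and in dmr_6 (1320 and 46.7, 66.3 to 238 on the other arrays). What these features measure is not given in the sources used here, and whether the difference is linked to the fall from 46 to 7 calls without WT/WT 1 was not tested.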

How the results depend on the processing

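Fits within 1 slide row, slide column, the filter of the authors' table (detected on all arrays of 1 group), scaling on low-numbered miRNAs, class centring and the miRNA without spread were chosen after the data were seen. For G93A/G93A against WT/WT (46) the count was 83 with array weights, 29 among miRNAs detected on all 8 arrays, 18 with class centring, 12 without a filter, 14 without scaling, 18 with only the 2 groups, 22 with scaling on low-numbered miRNAs, 7 with the slide row as a block, 3 within row 2, and 7 to 56 leaving out 1 array. For G93A/WT against WT/WT (21) it was 97 with array weights, 0 on all 8 arrays (limma, 103 unadjusted), 39 with the filter of the authors' table, 33 with the floor at the highest limit, 9 without a filter, 130 without scaling, 43 with only the 2 groups, 12 with low-numbered scaling, 4 with the authors' values, and 7 to 61 leaving out 1 array. For G93A/G93A against G93A/WT (57) it was 215 with array weights, 37 without a filter, 149 without scaling, 0 with the slide row as a block (limma, 73 unadjusted), and 37 to 121 leaving out 1 array. For the F test (77) it was 235 with array weights, 37 without a filter, 161 without scaling, 48 with quantile normalization, 50 with low-numbered scaling, 28 with the slide row as a block, and 41 to 125 leaving out 1 array. Lists passing between G93A/G93A and WT/WT (1) were 3 with array weights, 0 with an estimated correlation, 2 without a filter, 2 with quantile normalization, 2 with low-numbered scaling, 3 with the slide row as a block, 4 within row 2 and 1 to 5 leaving out 1 array (5 without G93A/G93A 3, 4 without WT/WT 1). Lists passing between G93A/G93A and G93A/WT (1) were 3 with array weights, on all 8 arrays, on at least 3 arrays, with the filter of the authors' table and with the slide row as a block, 2 with the highest floor, with a trended robust spread and with low-numbered scaling, 7 with quantile normalization, 4 with the authors' values, 0 with an estimated correlation and with class centring (0 and 2 unadjusted in camera), and 1 to 5 leaving out 1 array (5 without G93A/WT 1, 4 without G93A/G93A 3). Lists between G93A/WT and WT/WT stayed at 0 in the alternatives run with limma's camera or fry. The correlation of the 2 differences from WT/WT (0.495) ran from 0.374 to 0.580 leaving out 1 array, lowest without G93A/G93A 3 and highest without G93A/WT 2. A lone WT/WT array in these fits is assumed to vary like the other groups. Mean numbers of detected miRNAs moved by less than their spread in the alternatives run. A sign change counted as a reversal only where the main fit or the alternative passed. Without scaling 7 differences reversed by this rule, for G93A/WT minus WT/WT miR-411-3p (0.015), miR-181d-5p (0.10), miR-6947-5p (0.15) and miR-6960-5p (0.18), and for G93A/G93A minus G93A/WT miR-6947-5p (−0.13), miR-6960-5p (−0.068) and miR-30c-2-3p (−0.15). The median then lay at 0.79 and −0.68, so these reversals come from the missing scaling. Over named miRNAs and alternatives other than leaving out an array, 4400 kept their side of the threshold without such a reversal, 292 no longer passed and 129 newly passed. Over lists these were 580, 3 and 37. Sign changes with neither fit passing count among the 4400 and the 580. Leaving out the miRNA without spread gave 43, 22 and 57 calls and 76 in the F test. Filters, single rows and left-out arrays change how many miRNAs or samples are tested, and beyond that the cause was not tested. Signal over background limits the dim miRNAs: 12 of the 17 higher in G93A/WT than in WT/WT and 18 of the 28 lower in G93A/G93A than in G93A/WT are known only as bounds.

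With the replicate number as a block the counts were 10, 8, 37 and 37 (F test), and 5 and 2 lists passed in the comparisons of G93A/G93A with WT/WT and with G93A/WT. The labels do not say what a number shares. Same-numbered arrays deviated together with correlations of −0.347 to 0.211, and 1 of 8 arrays correlated best with its own number, so the numbers were not taken to pair the samples.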

Other observations

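The epithelial list and the tests on array brightness (for the epithelial miRNAs), slide row (for the detected set), probe class and neighbouring genes were chosen after the result was seen. The rules that decide on brightness, slide row and class shift were made stricter after the results were seen, in the direction of leaving an explanation open. The 2 arms of a precursor gave opposite calls in 1 case, miR-411 in G93A/WT against WT/WT. The tested miRNAs formed 426 pairs encoded within 10000 bases of each other, and 202 of these lay outside the largest neighbourhood, that of 34 tested miRNAs in the Dlk1-Dio3 locus. The Dlk1-Dio3 list held 44 tested miRNAs, so the 202 pairs may still include pairs of that locus. A hypothesis that neighbouring miRNAs shift together in the medium was tested on the 202 pairs, with 10000 permutations. Their differences were closer than those of random pairs in 1 of 3 comparisons, G93A/G93A against G93A/WT (permutation p = 0.0050), and not in the other comparisons (p = 0.339 and 0.616), which leaves the hypothesis open.

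The first pattern is the lower level of all 5 tested epithelial miRNAs in G93A/G93A medium. The median difference of the 5 was −2.76, while the scale factors of the 2 groups differed by 0.164 ± 0.213 (SE) on the log2 scale. The size of the decrease cannot decide on differing brightness of the arrays. The 5 were listed after their large decreases were seen, and most of them lay at the floor in G93A/G93A. The mean scale factor was 1.15 ± 0.168 in G93A/G93A and 1.28 ± 0.216 in WT/WT (SD), so the G93A/G93A arrays were not the dimmer ones on average. RNA from epithelial cells carried over from the dissected tissue in differing amounts stays open as a candidate explanation. Within groups, the 5 deviated together with a mean correlation of 0.274, below the 0.332 that marks the top 5 percent of 10000 random sets. Most of the 5 lay at the floor on every G93A/G93A array and so did not deviate there. The random sets were drawn from all tested miRNAs, so this comparison cannot decide. No member was detected on all arrays of both groups, so a result against carry-over could not have been reached. Of the 10 listed miRNAs 1 (miR-203-3p) is also in the inflammation list, and whether myocytes release these miRNAs themselves was not tested. The genotype, and different pups or cultures, stay open as well.

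The second pattern is the 21 miRNAs detected on every G93A/WT array and on no G93A/G93A array. Slide row as the whole cause is argued against, since WT/WT 1 and WT/WT 2, which lie in different rows, each detected 8 of the 21 (38.1%), a difference of 0 percentage points between slide rows. Of the 30 miRNAs of nearest level on the G93A/WT arrays, on average 58.7% (SD 12.9, range 46.7% to 93.3% over the 21) were detected on a G93A/G93A array. Other members of the 21 could be among these 30. They are undetected in G93A/G93A by the rule of the set, which can only lower the share, so the share cannot decide. Brighter G93A/WT arrays that lift dim miRNAs over the detection limit stay open. A difference between the co-cultures stays open beside this brightness.

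The third pattern is that 16 of the 20 higher calls in G93A/G93A against WT/WT were miRNAs numbered 1000 or above, while 25 of the 26 lower calls were numbered below 1000 (Fisher's exact test over these calls, p = 7.26e-08). Fisher's test counts the miRNAs as independent, which those of one family or locus are not. Of all tested miRNAs, 248 were numbered 1000 or above and 290 below. Their median differences in this comparison were 0.005 and −0.105. A like split was seen in G93A/G93A against G93A/WT, where 23 of 29 higher calls were numbered 1000 or above and 19 of 28 lower calls below. Slide row stays open: over the called miRNAs the difference between the WT/WT arrays of the 2 rows followed the group difference with a slope of 0.0968 ± 0.0299 (SE), where a row effect needs 2, but with that slope in each of them 0 of the 46 would have passed in limma, so the written expectation could not decide. With the row as a block 7 calls remained and all 46 kept their sign. The median size moved from 0.82 to 0.80 and the median SE rose from 0.145 to 0.169. This cannot decide either, because the block fit compares G93A/G93A with WT/WT 2 alone. The 46 were called where the 2 WT/WT arrays lay close (median absolute difference 0.104), so their differences had to hold. One shift of each probe class cannot be told apart from a change in these miRNAs: with each class centred on each array 18 of the 46 calls remained (Fisher's exact test of the split, p = 0.0186). All 46 kept their sign and the median size moved only from 0.82 to 0.75 while the median SE rose from 0.145 to 0.167, so the calls ended through a small loss in size and a larger error.

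For G93A/G93A against G93A/WT, the 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 57 calls and the highest other split gave 1. Each other split mixes the 2 groups, which raises the spread and lowers the calls. The real split is also the split by slide row, so these counts cannot tell a difference between groups from one between rows.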
